A study of Mus musculus with 24 samples.

How the data were processed

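RNA from sorted Peyer's patch FRCs and HEV endothelial cells of mice was sequenced in 24 libraries, 1 library per deposited file. Per the labels, 1000 cells per mouse were sorted, cDNA was made by template switching, libraries were built with a transposase kit and read pairs were sequenced on a HiSeq instrument. Per the submitters' processing notes, reads were aligned with GSNAP to the mouse build mm9. The protocol text of the labels names a human build instead, which was taken as a slip because the gene identifiers are those of mouse genes. Per the labels, reads of low quality and ribosomal or adapter reads were removed and uniquely mapped reads kept. No version of these tools or of the gene annotation is stated.

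Each deposited file holds, per the file headers, a read count and a second value for every gene model, of which there are 36528. The authors computed the second value as an RPKM scaled by a size factor of each library. Within each of 5674 genes it was checked to equal the count over the submitters' size factor, up to a constant of the gene, to a relative tolerance of 1e-06. The part of gene length in that constant was not checked. All results use the counts, and the RPKM values were used only in that check. Gene symbols were joined by gene identifier to RefSeq annotation of the mouse assembly GRCm38.p6, which named 85.0% of the identifiers, holding 97.3% of the reads. No coordinates are printed, because the annotation behind the counts is not stated. There were 29 gene models with exactly the counts of another model. The counts carry no strand information.

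Groups follow the cell type and treatment in the labels. Labels give each library a number and a pair of index sequences. The same 8 pairs recur in libraries 1 to 8, 9 to 16 and 17 to 24, which were therefore taken as 3 sequencing pools. The pool is inferred and not stated. The i5 index is unevenly spread. All FRC PEG libraries carry index 503, as do 3 of 7 FRC controls, and all HEV PEG libraries carry 504, as do 2 of 4 HEV controls. Nothing pairs FRC and HEV libraries by mouse, so no mouse term was used and they were treated as independent, which the labels do not settle.

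Counts were filtered with filterByExpr at its count minimum of 10, scaled by TMM and tested with the edgeR quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3; robust, two-sided) with the pool as covariate. A gene passed at a Benjamini-Hochberg adjusted p under 0.05. The comparisons were PEG against control in FRC (14 libraries), PEG against control in HEV (10), HEV against FRC among controls (11) and the difference of the PEG effect between HEV and FRC (24). SE is the log2 fold change over the square root of its F. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists of a comparison with at least 5 members tested. The 37 lists cover chemokines, matrix, mechanical and shear response, endothelial function, signalling, stress, metabolism and markers of other cell types. Marker levels are means of log2(CPM + 1), compared between PEG and control by exact permutation over all splits. Within a cell type, p-values measure the spread between libraries of different mice. Where both cell types enter, they measure the spread between libraries that may in part share a mouse. Reads are PCR copies without molecular identifiers, so counting intervals (exact binomial, 95%) and the floor of 3 counts cover counting error only.

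These choices were made before the data were examined, as was the rule for naming genes: the genes of smallest p with a symbol and a mean of at least 5 CPM, up to 8 higher and 8 lower where they pass, and otherwise those that pass filled up to 4 per direction, for each comparison with PEG; 6 higher and 6 lower between the cell types; genes of stromal and venule function listed in advance; and 2 to 4 members of smallest p of each list that passed. Near-identical paralogs and immunoglobulin or T cell receptor segments were left out of the ranking. A gene that the rule names is not reported here, and no other was put in its place. The genes named for the contrast of libraries 1 to 9 with libraries 10 to 24 lie outside this rule and were chosen after their values were seen: those called in both cell types, with a symbol and at least 5 CPM, ordered by the larger of the 2 p-values.

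Most alternatives changed 1 choice at a time: DESeq2 size factors or the submitters' size factors, no filter or a count minimum of 50, the DESeq2 Wald test (DESeq2 1.42.0) and limma-voom with quality weights, no covariate or pool plus i5 index, libraries of a single i5 index, all 24 libraries in 1 model, PEG libraries in place of controls, pseudocounts of 0.1 and 10 or summed CPM for marker levels, and each library left out in turn. The DESeq2 test also brought its own size factors and left some genes without an adjusted p, and limma-voom changed the test and the weights of libraries together. Alternatives added after the data were seen were a batch term for libraries 1 to 9 against 10 to 24, each of these sets alone, the epithelial marker level as a covariate, and the remaining settings for the gene lists. Permutation of marker levels over splits within pools was added then too. Each comparison was repeated on 100 splits of its libraries into groups of the same sizes (40 for the difference), the real split included. Recovery was tested on simulated data with known changes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.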

Results

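Stromal cells of the Peyer's patch, the lymphoid tissue of the small intestine wall, were profiled by RNA sequencing in mice that drank polyethylene glycol (PEG, 10% w/v, taken freely in the drinking water for 3 days) and in unperturbed mice. PEG is an osmotic agent, given here to lower fluid flow. For each mouse 1000 fibroblastic reticular cells (FRCs, the fibroblasts that build the conduit network and make lymphocyte-attracting chemokines) or 1000 endothelial cells of high endothelial venules (HEVs, the vessels through which lymphocytes enter) were sorted, per the labels, which do not say whether both cell types came from the same mice. FRC and HEV libraries were compared as independent samples. The 24 libraries comprise 7 FRC PEG, 7 FRC control, 6 HEV PEG and 4 HEV control libraries, named below by group and library number.

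Reads assigned to genes ranged from 15823379 to 21710946 per library in FRC PEG, from 12416032 to 18052362 in FRC control, from 14392146 to 17160900 in HEV control and from 3115003 to 19948766 in HEV PEG. HEV PEG library 16 held the 3115003, and the next lowest library of the series held 12416032. The median total was 16136689 reads. The median 95% confidence interval of a log2 fold change reached 0.78 to either side in FRC, 1.09 in HEV, 1.21 between the cell types and 1.44 for the difference of the PEG effects. Epithelial RNA varied strongly between libraries of every group. The mean log2(CPM + 1) of 24 intestinal epithelium markers ran from 0.81 to 5.03 in FRC control, from 1.52 to 7.55 in FRC PEG, from 0.40 to 5.05 in HEV control and from 0.70 to 6.59 in HEV PEG (CPM is the count scaled to the library total). Libraries 1 to 9 also stood apart from libraries 10 to 24 in both cell types. On the first principal component, which held 18.7% of the variance in FRC and 24.4% in HEV, the FRC scores of libraries 1 to 9 lay between -106.7 and -29.1 and those of libraries 10 to 24 between 17.0 and 89.3.

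**Figure D1:**
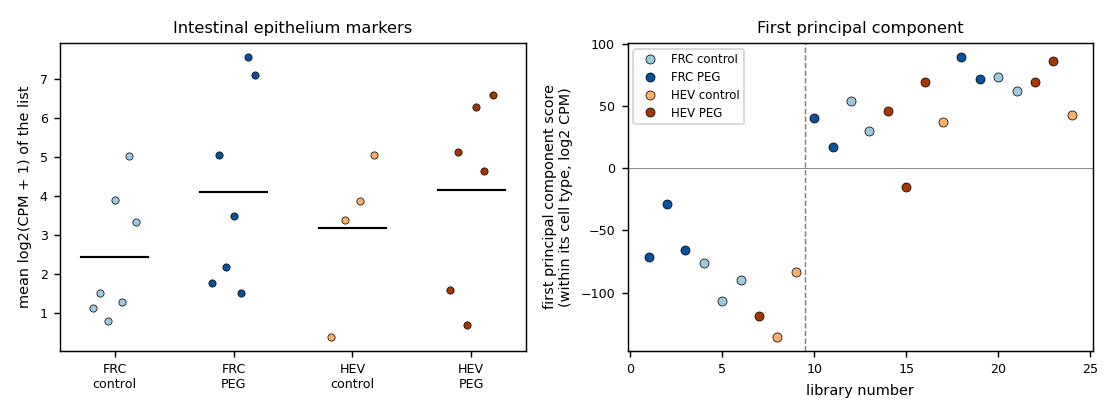
Left, mean log2(CPM + 1) of 24 intestinal epithelium markers in each library (points) with the group mean (bars). Right, first principal component score of each library within its cell type against library number, with a dashed line between libraries 9 and 10; every FRC library up to number 9 scored at or below -29.1 and every later FRC library at or above 17.0.

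The comparison of HEV with FRC controls asked how the sorted populations differ without PEG. HEV cells carried the vascular addressin Madcam1 (9864 ± 2334 CPM, SD, n = 4, against 76.4 ± 43.6, n = 7, in FRC), the mucin-like selectin ligand Glycam1 (5433 ± 2340 against 32.6 ± 59.6) and the endothelial junction protein Pecam1 (1030 ± 612 against 2.12 ± 3.17). FRCs carried the growth factor receptor Pdgfra (537 ± 87.8 CPM against 0.17 ± 0.089 in HEV), the FRC surface protein Pdpn (216 ± 15.4 against 0.070 ± 0.054), complement C3 (2016 ± 546 against 0.71 ± 0.098) and collagen Col1a1 (1817 ± 826 against 14.5 ± 25.9). Each of these 7 genes differed in all 4 HEV libraries from all 7 FRC libraries, with adjusted p from 4.33e-09 for Pdgfra and C3 to 0.0025 for Col1a1 (edgeR). Interferon-induced genes were prominent on the HEV side. The GTPases Gbp4 (log2 fold change 5.26 ± 0.21, SE) and Tgtp1 (4.15 ± 0.22) and the class I gene H2-Q6 (3.07 ± 0.14) were among the 6 higher genes of smallest p, beside the prostaglandin transporter Slco2a1 (4.35 ± 0.22), the sulfotransferase Sult1a1 (3.85 ± 0.20) and AU021092, which was at 335 ± 129 CPM in HEV and 0.096 ± 0.083 in FRC. On the FRC side the Wnt inhibitor Sfrp1 (1838 CPM against 11.4 ± 2.95; log2 fold change -7.23 ± 0.25), the matrix protease Mmp10 (824 ± 142 against 0.19 ± 0.17), Stc2 (523 ± 281 against 0.17 ± 0.13) and Medag (175 ± 42.9 against 0.068 ± 0.0060) completed the 6 lower genes of smallest p. The fitted folds of genes at this level in HEV depend on very few reads. Cdh5, an endothelial cadherin, was higher in HEV (log2 fold change 6.47 ± 1.07; 5.29 without HEV control 9) and Pdgfrb lower (-8.09 ± 1.15; from -9.67 without HEV control 17 to -7.30 without HEV control 8). Single libraries held most of the few reads of some markers in the other cell type: 2652 of 3679 Glycam1 reads of FRC controls were in library 20, and 881 of 945 Col1a1 reads of HEV controls in library 9. The leukocyte marker Ptprc (0.84 ± 1.80, adjusted p 0.80) and the epithelial marker Epcam (-0.98 ± 1.63, adjusted p 0.73) did not pass. With single libraries left out they ran from -1.52 to 1.47 and from -2.49 to 0.14. The HEV sulfotransferase Chst4 was below the filter on low counts, with 170 reads over the HEV controls and 3 over the FRC controls, a ratio of 101 (95% counting interval 34.1 to 497). All 3 FRC reads were in FRC control 13, without which it was at least 85.0-fold higher in HEV, and without HEV control 24 the ratio was 66.1. The T cell chemokine Ccl19 was below it too, with 77 reads over the FRC controls and 0 over the HEV controls, at least 14.3-fold higher in FRC.

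Of 15743 genes tested between the cell types, 1636 were higher and 2233 lower in HEV at an adjusted p under 0.05. All 22 pan-endothelial genes rose in HEV relative to FRC, among them Plvap, Ly6c1 and Erg (list adjusted p 2.98e-17, camera), and 17 of 18 pan-fibroblastic genes fell (1.29e-14; 18 adjusted over the list alone). In the antigen presentation and interferon-gamma list 21 of 27 genes were higher, including Gbp4, Irf1 and Tap1 (2.76e-09), and in the type I interferon list 16 of 28 were higher and 1, Ifi27l2a, lower (4.65e-05). HEV addressin and glycan genes were higher in 12 of 20 (6.76e-08), with Enpp2, Cd34 and the glycosyltransferase Gcnt1 beside Madcam1. Genes of the laminar shear response, including Klf2, Cav1 and Slco2a1, were higher in 15 and lower in 2 of 24 (7.70e-08), and leukocyte adhesion genes such as Icam1 and Jam2 were higher in 15 and lower in 2 of 23 (6.02e-06). The shear list shares members with the pan-endothelial, addressin and adhesion lists. Its rise between these cell types does not tell a shear response from endothelial identity. FRCs were higher in collagens and conduit matrix (29 of 34, with Fn1 and Lama2, and 1 gene higher in HEV; 2.27e-12), in matrix remodelling enzymes (21 of 30 against 4 higher in HEV; 3.01e-09), in pericyte genes (5 of 11, against 1 higher in HEV; 0.00032), in TGF-beta response genes (14 of 25 against 2; 0.0020) and in stromal chemokines and cytokines (15 of 25, including Cxcl13, Ccl7 and Cxcl12, against 5; 0.0032). These 12 lists also passed with an estimated correlation. Another 5 passed with the preset correlation alone. Smooth muscle genes were lower in 17 of 18 (adjusted p = 0.071 with an estimated correlation) and YAP and TAZ targets were lower in 11 and higher in 4 of 22 (adjusted p = 0.071 with an estimated correlation). The NF-kappaB list was higher in 14 and lower in 6 of 28 (adjusted p = 0.078 with an estimated correlation), with a median of 0.86 and a mean of -0.33, Ccl7 being far lower in HEV. Immediate early genes were higher in 10 and lower in 4 of 28 (adjusted p = 0.28 with an estimated correlation) and unfolded protein response genes were higher in 6 of 24 (adjusted p = 0.072 with an estimated correlation). With libraries 10 to 24 alone, a choice made after the data were seen, 2276 genes passed, and with libraries 1 to 9 alone 1477.

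**Figure D2:**
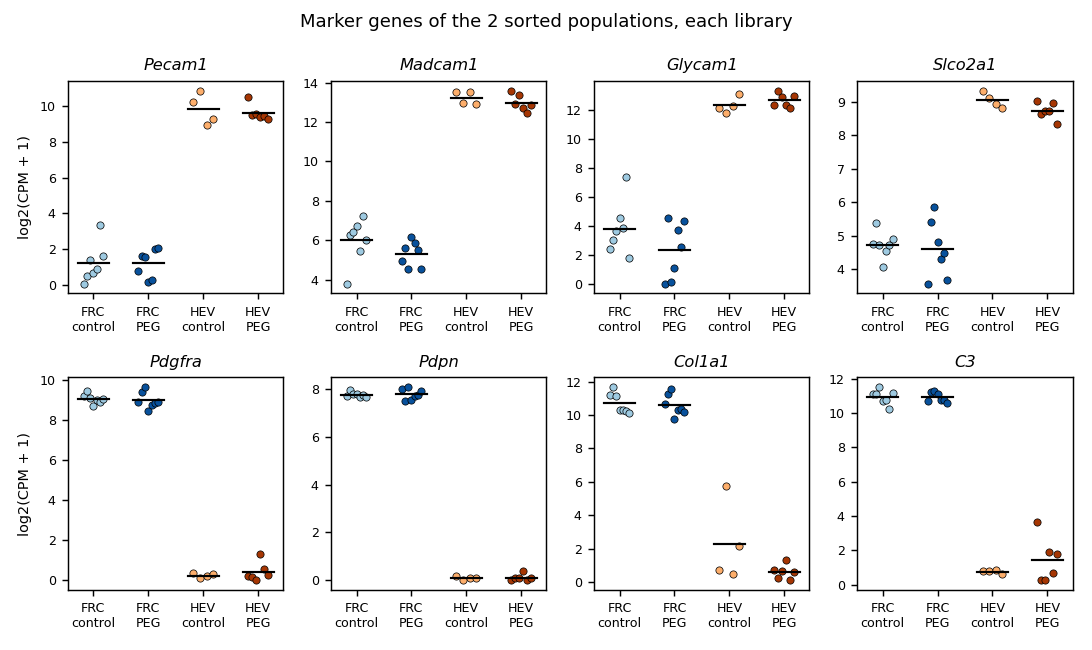
Expression of 8 marker genes as log2(CPM + 1) in each library (points) with the group mean (bars) in the 4 groups. Pecam1, Madcam1, Glycam1 and Slco2a1 were higher in every HEV library than in every FRC library, and Pdgfra, Pdpn, Col1a1 and C3 lower.

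The comparison of PEG with control FRCs asked what differs under PEG in the fibroblasts of the patch. The data hold no measure of fluid flow, so effects of flow and other effects of PEG cannot be told apart. No single gene passed correction across 14595 genes (edgeR, smallest adjusted p 0.12), and the values below describe the genes of smallest p. Eif3l (gene ID 223691), a subunit of a translation initiation factor, was at 260 ± 51.5 CPM (SD, n = 7) in PEG and 140 ± 12.4 (n = 7) in control, a log2 fold change of 0.89 ± 0.14 (SE, adjusted p 0.12). Gpx3 (14778), a secreted glutathione peroxidase, was at 3170 ± 193 CPM against 2075 ± 480 (0.64 ± 0.11, adjusted p 0.24). For both genes all 7 PEG libraries lay above all 7 controls. The glycolytic enzyme Aldoa (0.50 ± 0.10) and the collagen-processing cofactor Pcolce2 (1.56 ± 0.32) followed. On the lower side were lipoprotein lipase Lpl (16956), at 246 ± 54.9 CPM against 393 ± 80.2 with all 7 PEG libraries below all controls (-0.69 ± 0.15), Mxra7 (-0.82 ± 0.18), the polymerase subunit Polr2b (-0.57 ± 0.13) and the calcification inhibitor Mgp (-0.52 ± 0.12), each with an adjusted p of 0.48.

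Among the FRC genes chosen beforehand, the chemokine Cxcl12 was higher in PEG by 0.35 ± 0.12 on the log2 scale (p 0.012, adjusted p 0.62), above the control median in 7 of 7 libraries, and the B cell survival factor Tnfsf13b by 0.41 ± 0.18 (p 0.038, adjusted p 0.70). The stretch-activated channel Piezo1 (-0.68 ± 0.31, p 0.048) and the marginal reticular cell marker Madcam1 (-0.88 ± 0.41, p 0.049) were lower, with adjusted p of 0.73 each. Pan-endothelial markers were lower as well, at a mean level of 2.22 ± 0.40 (SD, n = 7) in PEG and 2.79 ± 0.90 (n = 7) in control (exact permutation p 0.15, adjusted p 0.60). Exact permutation within sequencing pools, a test added after the data were seen, gave p 0.05 (adjusted p 0.30). FRC control 20 held the highest level of these markers (4.24) and of Madcam1 (149 CPM) among the FRC libraries. The values were 0.14 ± 0.20 for Vcam1, 0.04 ± 0.12 for Pdpn, -0.02 ± 0.15 for Icam1, -0.11 ± 0.43 for the lymphocyte survival factor Il7, -0.16 ± 0.35 for the B cell chemokine Cxcl13, -0.63 ± 0.74 for Tnfsf11 and 0.29 ± 0.68 for Ccl21a, whose mean was 1.79 CPM. Ccl21a has near-identical paralogs and only uniquely mapped reads were kept, so its counts may understate its expression. With single libraries left out Piezo1 ran from -0.79 to -0.42 (without FRC control 5), Tnfsf11 from -0.91 to -0.29 (without FRC control 4) and Ccl21a from 0.075 (without FRC PEG 11) to 0.60 (without FRC control 20). Vcam1, Pdpn, Icam1, Il7 and Cxcl13 changed sign. Ccl19 was below the filter on low counts, with 77 reads over the 7 controls and 53 over the 7 PEG libraries.

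Of the 33 lists tested in FRC, 3 passed with the preset correlation, 0 with an estimated one and 0 by fry. The TGF-beta response list was lower in PEG (adjusted p 0.018; adjusted p = 0.43 with an estimated correlation), with 17 of 25 members negative and a median log2 fold change of -0.23. None of them passed among all genes and 2 did adjusted over the list alone. Among its members of smallest p were the activin subunit Inhba (-1.76 ± 0.45), the feedback inhibitor Pmepa1 (-0.78 ± 0.22) and Ccn2 (-0.88 ± 0.33), each below the control median in 7 of 7 PEG libraries. The collagens and conduit matrix list was also lower (adjusted p 0.023; adjusted p = 0.43 with an estimated correlation), with 29 of 34 negative, a median of -0.15 and 4 past adjusted over the list alone. The mean level of the collagen list was below the control median in 4 of 7 PEG libraries, and that of the TGF-beta list in 6 of 7. Its members went both ways: Col5a2 (-0.51 ± 0.13) and Tnc (-0.41 ± 0.13) were lower, while the proteoglycan Dcn (0.56 ± 0.13, all 7 PEG libraries above all controls) and Fbln1 (0.34 ± 0.10) were higher. Intestinal epithelium markers were higher in PEG (adjusted p 8.39e-07; adjusted p = 0.43 with an estimated correlation), with 20 of 20 positive, a median of 1.78 and 2 past adjusted over the list alone. Examples are Cdh1 (4.16 ± 1.11), Lgals4 (1.49 ± 0.44), Vil1 (3.32 ± 1.14) and Tff3 (5.25 ± 1.91; 2.43 without FRC PEG 2 and 6.91 without FRC control 12). Without FRC PEG 2 Vil1 was at 2.28. Their mean level per library was 4.09 ± 2.52 (SD, n = 7) in PEG and 2.43 ± 1.64 (n = 7) in control (exact permutation test, two-sided, p 0.17, adjusted p 0.60). Exact permutation within sequencing pools, a test added after the data were seen, gave p 0.044 (adjusted p 0.30). The epithelial signal thus moved with PEG alongside the TGF-beta and collagen lists. With the epithelial level in the model, a choice made after the data were seen, the TGF-beta list had a median of -0.21 with 18 of 25 negative (adjusted p 0.23) and the collagens a median of -0.12 with 26 of 34 negative (adjusted p 0.30). The median standard error of their members went from 0.25 to 0.32 and from 0.14 to 0.18. All 5 libraries 10, 18, 19 (PEG), 20 and 21 (control) mattered to both calls. Without them in turn the TGF-beta adjusted p was 0.073, 0.055, 0.076, 0.12 and 0.063, and the collagen one 0.073, 0.064, 0.076, 0.090 and 0.10. FRC PEG 10, 18 and 19 also had the highest shares of mitochondrial reads among FRC libraries (1.71%, 1.65% and 2.24%). The next highest was 1.29%, in FRC control 6. The part of this share in the calls was not tested. The number of lists called was 8 without FRC control 4, 6 without FRC PEG 2 and 5 without FRC control 6 or 13. With libraries 1 to 9 alone, again chosen after the data were seen, the TGF-beta and collagen lists pointed the other way (adjusted p 0.89 and 0.996). With libraries 10 to 24 alone both were lower (0.00069 and 0.0014). The collagen call also ended with no covariate (0.067), with the i5 index added (0.10), among libraries of a single i5 index (0.13) and with all 24 libraries in 1 model (0.10). The epithelial call ended with the i5 index added (0.10). No other list passed with all libraries. Genes of focal adhesion and actin linkage (adjusted p 0.098), the Notch pathway (0.10), mechanosensitive channels (0.11) and stromal chemokines and cytokines (0.67) were among them.

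At an unadjusted p under 0.05 there were 989 genes in FRC, where evenly spread p-values would give 730. With no covariate there were 667 and with the epithelial level in the model 689. Libraries 10 to 24 alone gave 1589, beside 768 from evenly spread p-values, and libraries 1 to 9 alone 558, beside 718. DESeq2 called 55 genes (28 higher, 27 lower) and limma-voom with quality weights 26 (21 higher, 5 lower) in the same libraries, and edgeR without a filter on low counts called 177. On simulated data of this size, 2-fold changes in genes above 5 CPM were recovered in 16.2% and 4-fold changes in 59.5% of cases.

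**Figure D3:**
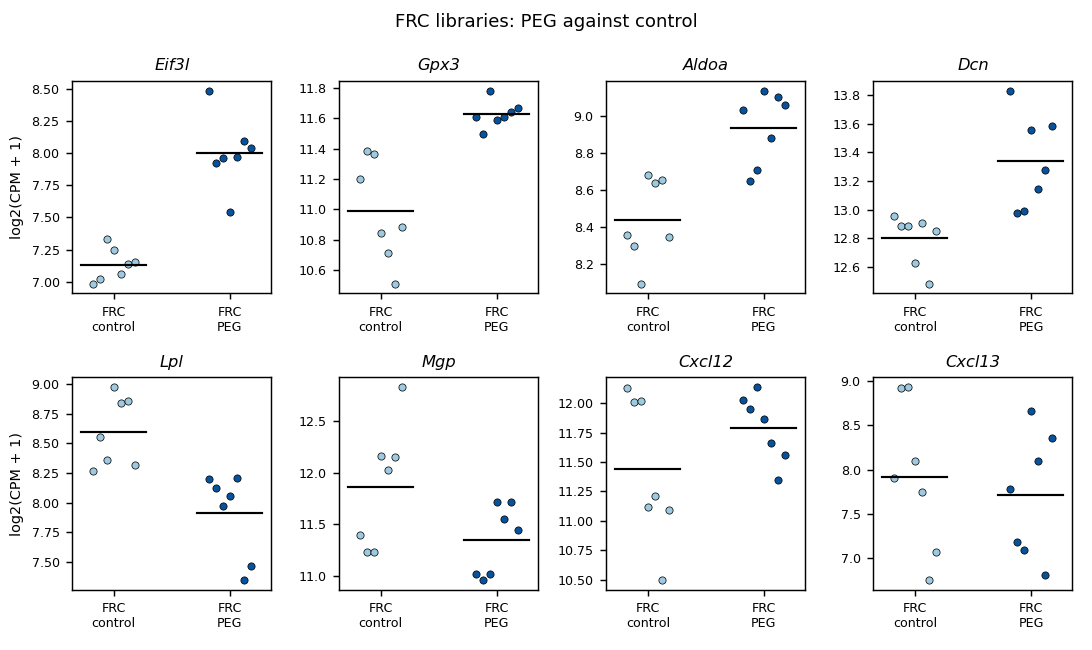
Expression of 8 genes as log2(CPM + 1) in each FRC library (points) with the group mean (bars), PEG against control. Eif3l, Gpx3 and Dcn were higher and Lpl lower in all 7 PEG libraries than in all 7 controls, and none of the 8 passed correction over all genes in edgeR.

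The comparison of PEG with control HEVs asked the same of the venules. No gene passed correction across 14308 genes (edgeR, smallest adjusted p 0.64), with 6 PEG and 4 control libraries. The genes of smallest p were of low or scattered expression. The receptor chain Il13ra1 (16164) had 39 to 428 reads per PEG library and 545 to 1242 per control (log2 fold change -2.73 ± 0.45, SE), and the growth factor Pdgfc had 2 to 55 against 277 to 681 (-4.44 ± 0.86; -3.25 without HEV control 9). For Dtnb (-5.55 ± 1.09) all 6 PEG libraries were likewise below all 4 controls, and for the endocytic adaptor Sh3gl1 (-1.45 ± 0.27) 5 of 6 were. Zfp27 had 57 to 931 reads in PEG and 5 to 54 in control (4.98 ± 0.86), Mettl25 31 to 628 against 1 to 128 (3.35 ± 0.73), and Tmem45b, an epithelial gene, 0 to 1196 against 0 to 3 (7.87 ± 1.42; 5.93 without HEV PEG 22). The T cell costimulatory receptor Cd28 had 913 reads over the PEG libraries and 1 over the controls, a ratio of 703.3 in CPM with a 95% counting interval from 126 to 27810. HEV PEG 22 held 418 of the 913 reads, and without it the ratio was 452. Without HEV control 24, which held the 1 read, Cd28 was at least 180-fold higher in PEG. The mean level of T cell and innate lymphoid markers in HEV was 1.30 ± 0.39 (SD, n = 6) in PEG and 1.22 ± 0.21 (n = 4) in control (exact permutation p 0.76). In FRC, Cd28 was at 8.64 ± 3.54 CPM in PEG and 4.80 ± 5.15 in control (n = 7 each). Each of these 8 genes had an adjusted p of 0.64, save Mettl25 at 0.77.

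Among the HEV genes chosen beforehand, E-selectin (Sele), an adhesion receptor of activated endothelium, was at 1697 ± 1215 CPM (SD, n = 6) in PEG and 767 ± 268 (n = 4) in control (log2 fold change 1.11 ± 0.49, SE, p 0.042, adjusted p 0.79 in edgeR), above the control median in 5 of 6 libraries. The flow-induced transcription factor Klf2 (0.28 ± 0.23) and the nitric oxide synthase Nos3 (0.30 ± 0.32) did not pass, nor did Glycam1 (0.35 ± 0.30), Madcam1 (-0.20 ± 0.20), the glycosyltransferases Gcnt1 (-0.60 ± 0.29) and Fut7 (-0.54 ± 0.42), the sphingosine kinase Sphk1 (-0.65 ± 0.36), Selp (-0.22 ± 0.29), Vcam1 (-0.08 ± 0.31), Icam1 (-0.02 ± 0.20), Piezo1 (-0.08 ± 0.23), Ccl21a (1.06 ± 1.10) or Chst4 (1.53 ± 2.94; between -0.52 and 3.64 with single libraries left out). Without HEV control 9 Klf2 was at 0.014, Nos3 at 0.011 and Ccl21a at 0.49. The limit on Ccl21a counts given for FRC holds in HEV too. With single libraries left out Fut7 ran from -1.01 (without HEV control 8) to -0.17 (without HEV PEG 22), Sphk1 from -1.05 (without HEV control 8) to -0.33 (without HEV control 9), Gcnt1 up to -0.36 (without HEV control 24) and Madcam1 up to -0.024 (without HEV control 17). Glycam1, Selp, Vcam1, Icam1 and Piezo1 changed sign. The 95% intervals of Klf2 (-0.22 to 0.78) and Madcam1 (-0.65 to 0.24) exclude a change of 2-fold, also with each library left out in turn (up to 0.99 for Klf2 and down to -0.89 for Madcam1). None of 34 lists passed with either correlation of camera or by fry. The laminar shear response had a median of 0.0063 and a mean of -0.013, with 12 of 23 positive and the test pointing down (adjusted p 0.96). The addressins and glycan synthesis list had a median of -0.0029 and a mean of 0.073, with 9 of 21 positive and the test pointing down (0.74). Without HEV PEG 7 camera called 4 lists, without HEV PEG 22 or HEV control 8 it called 2, and without HEV PEG 15 it called 1. Epithelial markers were positive in 20 of 21 with a median of 1.65 (0.20), and their mean level was 4.15 ± 2.46 (n = 6) in PEG and 3.17 ± 1.98 (n = 4) in control (exact permutation p 0.51). There were 886 genes at an unadjusted p under 0.05, where evenly spread p-values would give 715. With no covariate there were 619, and with the i5 index added 632. A batch term for libraries 1 to 9 against 10 to 24 in place of the pool, chosen after the data were seen, gave 560. Libraries 10 to 24 alone gave 997, beside 793 from evenly spread p-values. Libraries 1 to 9 hold 1 of 6 HEV PEG and 2 of 4 HEV control libraries, and the pool term places HEV control 9 with libraries 10 to 16. DESeq2 called 116 genes (77 higher, 39 lower), limma-voom 0, edgeR without the filter on low counts 141, and edgeR with all 24 libraries in 1 model 18. Simulated 2-fold changes were recovered in 1.75% and 4-fold changes in 33.5% of cases, so most changes of such size were not detectable here.

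The last comparison asked whether PEG acts differently in the venules than in the fibroblasts, by testing the difference of the PEG effects over all 24 libraries. It called 2 genes of 18203, both higher in HEV PEG relative to HEV control. Rragd (52187), a GTPase that links amino acids to mTORC1, had 4 to 83 reads in each of the 6 HEV PEG libraries and 0 reads in all 4 HEV controls, while it was abundant in FRC with and without PEG (27.5 ± 12.8 and 28.9 ± 8.08 CPM, SD, n = 7 each). The difference had an adjusted p of 0.021. In HEV it was at least 57.8-fold higher with PEG, taking as the floor 3 reads over the control group, and did not pass in HEV alone (adjusted p 0.77). Flnc (68794), an actin-crosslinking filamin, was at 2.18 ± 1.74 CPM (n = 6) in HEV PEG and 0.11 ± 0.10 (n = 4) in HEV control, above all controls in 6 of 6, with a log2 fold change of -0.48 in FRC (difference of log2 fold changes 4.57 ± 0.75, SE, adjusted p 0.023; 5.34 without HEV control 9). In HEV alone its adjusted p was 0.79. Both are far more abundant in FRC than in HEV. The mean level of pan-fibroblastic markers was 1.18 ± 0.39 in HEV PEG and 1.59 ± 0.68 in HEV control (exact permutation p 0.28), with HEV control 9 at 2.60 and the other HEV controls from 1.16 to 1.35. With libraries 10 to 24 alone, a choice made after the data were seen, PEG minus control was -0.014. The count rested on single libraries. It was 16 without HEV control 8, 9 without HEV control 17, 6 without HEV control 24 and 5 without HEV PEG 7 or 22. It was 1 without HEV control 9, FRC PEG 2 or 11, or FRC control 6, 20 or 21.

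The next genes did not pass. The Notch ligand Jag1 was lower in FRC PEG (-1.11 ± 0.27) and higher in HEV PEG (0.75 ± 0.28), a difference of 1.85 ± 0.38 (adjusted p 0.12), and Spg21 went the other way (0.83 ± 0.21 in FRC, -0.94 ± 0.29 in HEV, difference -1.74 ± 0.32, adjusted p 0.068). For Jag1, 7 of 7 FRC PEG libraries were below the FRC control median and 5 of 6 HEV PEG libraries above the HEV one. Nol3, a cell death inhibitor, had 7 to 265 reads in HEV PEG and 0 to 6 in HEV control (difference 6.25 ± 1.24, adjusted p 0.085; 9.87 without HEV control 17). The macrophage complement gene C1qb (adjusted p 0.068) had 0 reads in all 6 HEV PEG libraries, and was at least 318-fold higher over the HEV controls, where libraries 8 and 9 held nearly all 736 reads (at least 171-fold without HEV control 8). These libraries also had the highest levels of myeloid markers in HEV (2.17 and 2.19), which were at 1.23 ± 0.25 (SD, n = 6) in PEG and 1.69 ± 0.58 (n = 4) in control (exact permutation p 0.14, adjusted p 0.89). Both are the HEV controls among libraries 1 to 9. With libraries 10 to 24 alone, a choice made after the data were seen, the myeloid level in PEG minus control was -0.060 (exact permutation p 0.81). The contractile protein Cnn1 (adjusted p 0.085), with nearly all of its 861 HEV control reads in library 9, had 1 read over HEV PEG, a ratio of 1118 (95% counting interval 200.1 to 44197; fitted difference -8.85). Without HEV control 9 the ratio was 57.4 and the fitted difference -5.08, and without HEV PEG 23 it was at least 306-fold higher in HEV control. The glypican Gpc3 (adjusted p 0.068) had 314 reads over HEV control, 172 of them in library 9, and 2 over HEV PEG, a ratio of 204 (56.0 to 1690; 127 without HEV control 9, 307 without HEV PEG 15 and 334 without HEV PEG 23).

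Of 37 lists tested for the difference, 2 passed with the preset correlation, 0 with an estimated one and 0 by fry. The TGF-beta response list was higher in HEV relative to FRC (adjusted p 0.0099; adjusted p = 0.64 with an estimated correlation), with 19 of 25 members positive, a median of 0.73 and 0 past either among all genes or adjusted over the list alone. In HEV alone its median was 0.39 and in FRC alone -0.23. Bmp4 (1.24 ± 0.37), the latency protein Ltbp1 (1.43 ± 0.46) and Id2 (0.89 ± 0.32) were positive, and Inhba, with 138 reads over the HEV controls, 135 of them in library 17, and 1 over HEV PEG, was negative (ratio 179, 95% counting interval 31.6 to 7126; at least 46.5-fold without HEV PEG 14). Without HEV control 17 its fitted difference was -0.26, from 3 reads against 1. The mean level of the list was above the HEV control median in 5 of 6 HEV PEG libraries and below the FRC control median in 6 of 7 FRC PEG libraries. Without HEV control 8 its adjusted p was 0.052. With libraries 1 to 9 alone it pointed the other way (0.895). Cytosolic ribosomal protein genes were also higher in HEV relative to FRC (adjusted p 0.0099; adjusted p = 0.83 with an estimated correlation), with 58 of 82 positive, a median of 0.29 and 0 past adjusted over the list alone. Rpsa (1.01 ± 0.40), Rpl22l1 (0.99 ± 0.40; 0.63 without HEV control 9) and Rpl36 (1.18 ± 0.51) were positive and Rpl15 (-1.05 ± 0.43) negative. This call was lost without HEV PEG 14 (adjusted p 0.054), HEV PEG 15 (0.052), FRC control 21 (0.11) or HEV control 9 (0.24). It was also lost with the i5 index in the model (0.46), the batch term for libraries 1 to 9 against 10 to 24 (0.081) or either of these sets alone (0.895 and 0.061). The number of lists called was 5 without HEV PEG 22, 4 without FRC PEG 3 or 19, FRC control 4, 5 or 12, HEV PEG 7 or 23 or HEV control 8, and 1 without HEV PEG 14 or 15 or FRC control 21. At an unadjusted p under 0.05 there were 1834 genes. DESeq2 called 360 and limma-voom 0. In edgeR the number was 38 without the filter on low counts, 5 with no covariate, 0 with the i5 index beside the pool, 7 with the batch term, 0 with libraries 10 to 24 alone and 19 with libraries 1 to 9 alone. Simulated differences of 4-fold were recovered in 14.2% of cases.

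**Figure D4:**
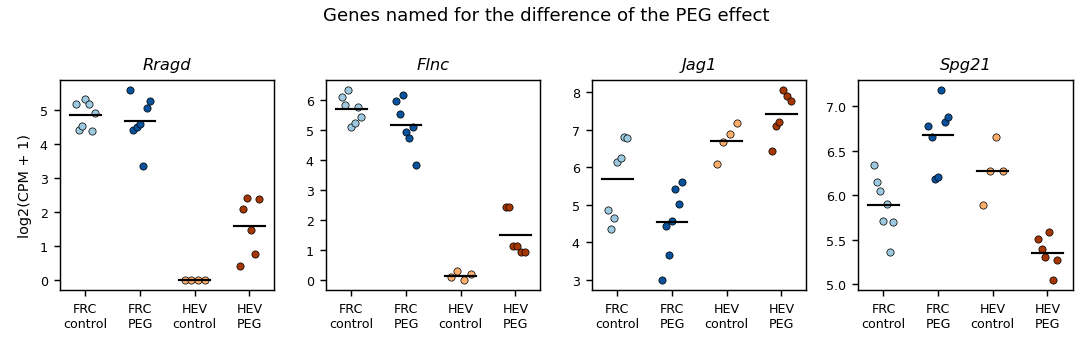
Expression of Rragd, Flnc, Jag1 and Spg21 as log2(CPM + 1) in each library (points) with the group mean (bars) in the 4 groups. Rragd and Flnc were higher in all 6 HEV PEG libraries than in all 4 HEV controls, and Jag1 and Spg21 did not pass the test of the difference.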

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

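All counts over other splits of the libraries, except those within pools, were tests chosen after the result was seen, as were the tests of epithelial RNA and the i5 index fits of the TGF-beta and epithelium lists. The other tests of the i5 index and the splits within pools for genes and lists in FRC were set down before.

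In 272 groups of 4 to 7 libraries, the highest or lowest library was compared with its nearest neighbour as a share of the group's range (Dixon's test at 95%), and 23 groups held a library far from the others, where chance gives about 1 in 20, or 13.6. Of these, 1 concerned depth and quality, 6 marker lists and 16 named genes. FRC control 20 was the far library most often, 4 times. The share of reads in the 20 most abundant genes was lowest in HEV PEG 22 (Dixon ratio 0.746). Marker levels stood apart for B cells in FRC PEG 10 (0.677), erythroid cells in FRC control 6 (0.686) and FRC PEG 3 (0.592), follicular dendritic and marginal reticular cells in FRC control 20 (lowest, 0.575), fibroblasts in HEV control 9 (0.869) and plasma cells in FRC control 6 (0.684).

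Among named genes in FRC, the far library was PEG 19 for C1qb (lowest, 0.577), PEG 1 for Il7 (lowest, 0.596), PEG 3 for Inhba (lowest, 0.680), PEG 18 for Nol3 (lowest, 0.602), control 6 for Rpl15 (lowest, 0.574), and control 20 for Ccl21a (highest, 0.722), Cdh1 (highest, 0.623) and Sult1a1 (highest, 0.622). In HEV it was control 8 for Epcam (lowest, 0.957), PEG 7 for Id2 (lowest, 0.704), control 17 for Inhba (highest, 0.944) and control 9 for Sphk1 (highest, 0.871). A ratio of 1, with the other libraries of the group all at 0, was found for Cd28 in HEV control 24, Cnn1 in HEV PEG 23, Inhba in HEV PEG 14 and Nol3 in HEV control 17, of which the first 3 rest on 1 read each.

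The PEG effect differed between HEV and FRC in the test of the difference for Rragd (adjusted p 0.0208), Flnc (0.0234), the TGF-beta response list (0.00992) and the cytosolic ribosomal protein list (0.00992). The calls of both lists were lost in other tests (adjusted p = 0.64 and 0.83 with an estimated correlation, 0.24 and 0.46 by fry). Chance cannot be excluded for the number of genes, since 16 of 40 splits gave at least the 2 genes of the real split, with up to 13 in another split, nor for the number of lists (28 of 40 splits gave at least 2, up to 9). Why another split called 13 genes was not tested. For the TGF-beta list, 2 of 40 splits gave a camera p as small as the real 0.000346, the smallest other being 4.4e-05, and for the ribosomal list 9 of 40 gave one as small as 0.000536 (smallest other 1.47e-08), so chance cannot be excluded there either. The 1834 genes at an unadjusted p under 0.05 were reached by 1 of 40 splits, the real one. That does not exclude chance for this count, since another split came close and no splits were drawn within pools for the difference. With the i5 index added the count was 1395, within the range of the other splits. The other splits gave from 1085 to 1793, all above the 910 of evenly spread p-values, so the 910 is no measure of chance in these libraries. For the numbers of genes called within a cell type, the count of splits has a fixed outcome and tests nothing, since all 100 of 100 splits must give at least the 0 genes of the real split in FRC (highest other 1) and in HEV (highest other 2), edgeR calling 989 and 886 genes at an unadjusted p under 0.05 there, DESeq2 55 and 116 genes and limma-voom 26 and 0 past correction. The 886 in HEV were reached by 9 of 100 splits (highest other 1232), so chance cannot be excluded for them. For HEV against FRC controls, 1 of 100 splits, the real one, gave 3869 genes (highest other 0). The other splits mix the cell types within a group, which widens its spread and makes a count of 0 likely. At an unadjusted p under 0.05 the real split gave 5492 genes (highest other 2194), so chance is excluded for the number of genes. The 17 lists were reached by 1 of 100 splits, the real one. Another split came close with 16, and no splits were drawn within pools, so chance is not excluded for the lists. The number of lists called in FRC was reached by 18 of 100 splits (real 3, highest other 7), so chance cannot be excluded for it. For the collagen list in FRC 1 of 100 splits, the real one, gave a camera p as small as 0.00213 (smallest other 0.00345), but within pools 5 of 100 did (smallest other 0.000599), so chance cannot be excluded once pools are balanced.

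Small p-values were more frequent in FRC PEG against control than evenly spread p-values give, at 6.78% of genes. With the pool in the model, 1 of 100 splits, the real one, gave as many genes (989, highest other 859). Among splits within pools 2 of 100 did, and the other one gave more (1073). So few splits argue against chance for this count but do not exclude it. The i5 index, which all PEG libraries share with 3 of 7 controls, stays open. These 3 controls against the other 4 gave 3.29% of genes, on fewer libraries. Among the libraries that share the index, however, the real split was matched by 11 of 100 splits (975 genes, highest other 1880). What set the highest of these splits apart was not tested. Epithelial RNA stays open too. With the epithelial level in the model 689 genes were left, beside 667 with no covariate and 810 with the index in the model. Whether an excess remains there is not known, since no splits were run in these models. In the main model the other splits gave from 302 to 859. Most lay below the 730 of evenly spread p-values, so the 730 is no measure of chance here. Libraries 10 to 24 alone gave 1589 genes and libraries 1 to 9 alone 558, and a batch term for these sets left 996. Neither set was compared with splits of its own libraries. The sets also differ in size, and the fit of libraries 1 to 9 had no pool term, so where the excess lies cannot be told. PEG is a further open explanation, as the epithelial level and the index both go with it in part.

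Intestinal epithelium markers were higher in FRC PEG libraries by the preset camera test (p 2.54e-08; adjusted p = 0.43 with an estimated correlation and 0.26 by fry). Chance cannot be excluded, since 8 of 100 splits gave a p as small (smallest other 3.97e-14). RNA from epithelial cells is a likely source, as 95.8% of 24 tested genes of a separate epithelial list, which shares no gene with the markers or with the other fixed lists, were positive too (median 1.95) and their level followed the markers across the 14 FRC libraries (Spearman rho 0.978, permutation p 1e-04, the smallest the permutations can give; Pearson r 0.985, and 0.976 without the 2 farthest libraries), with 18018 reads of Lgals4 and 11980 of Epcam in FRC PEG 18. The i5 index cannot be told apart from PEG: the level was 3.36 ± 2.00 (SD, n = 3) in FRC controls with the index of the PEG libraries and 1.74 ± 1.10 (n = 4) in the others, a difference of 1.62 beside 1.66 for PEG against control (exact permutation p 0.23 over 35 splits), and the call ended with the index in the model (median 0.79, adjusted p 0.103, beside 1.78 without it). Among the libraries of that index the list was still higher (median 1.16, adjusted p 0.0275, in a range from 1.64e-12 to 0.89 over all alternatives), but 39 of 100 splits of these gave a camera p as small. A change of the epithelium under PEG that alters what is carried into the FACS sort is a biological explanation that stays open and untested.

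The TGF-beta response list was lower in FRC PEG libraries by the preset camera test, and the call was lost in other tests (adjusted p = 0.43 with an estimated correlation, 0.26 by fry). Over all splits 2 of 100 gave a camera p as small as 0.00111 (smallest other 0.000376), while within pools 7 of 100 did (smallest other 0.00015), so chance cannot be excluded once pools are balanced. With the i5 index in the model the list was still lower (median -0.30, preset camera adjusted p 0.0197). Among libraries with the index of the PEG libraries it was lower too (median -0.33, adjusted p 0.0275). There 6 of 100 splits gave a camera p as small, so chance cannot be excluded for that difference. The i5 index as the whole cause therefore stays open. The adjusted p ranged from 0.00069 to 0.89 over all alternatives of this list. Epithelial RNA cannot be told apart from PEG: with the epithelial level in the model the median was -0.21 (interquartile range -0.44 to 0.04), beside -0.23 (-0.57 to 0.04) without it, and the call ended (adjusted p 0.233) as the median standard error went from 0.245 to 0.316. A lower TGF-beta response of FRCs under PEG may therefore be present, as a hypothesis that these libraries leave open.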

How the results depend on the processing

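The settings for libraries 1 to 9, libraries 10 to 24, the batch of these sets and the epithelial marker level were chosen after the data were seen. So was the permutation of marker levels within pools. Between HEV and FRC controls, 22 of 24 alternatives for the number of genes stayed within 1.5 times the 3869, and all 24 for the number of lists did. Of 89 values of named genes, 21 passed in their comparison. None of the 21 changed sign in any alternative, and 17 of them passed in every one. Across 2441 alternative values there were 71 sign changes, in 19 genes that had not passed. The scalings moved the median of all genes by 0.037 or less on the log2 scale. The cause of the differences below was not tested, except that subsets of libraries hold fewer libraries and the absence of a filter adds genes of very low count.

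Numbers of genes past correction moved as follows. In FRC, from 0, they were 177 with no filter, 55 with DESeq2 and 26 with limma-voom (989 at an unadjusted p under 0.05 in edgeR). In HEV, from 0, they were 141 with no filter, 116 with DESeq2 and 18 with all 24 libraries in 1 model (886 unadjusted; limma-voom 0). For the difference, from 2, they were 38 with no filter, 360 with DESeq2, 0 with limma-voom (1564 unadjusted), 5 with no covariate, 0 with the i5 index added (1395 unadjusted), 7 with the batch, 0 with libraries 10 to 24 and 19 with libraries 1 to 9, and from 1 to 16 with single libraries left out. Between the cell types they were 2276 with libraries 10 to 24 and 1477 with libraries 1 to 9.

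Numbers of lists moved in FRC, from 3, to 5 with no filter, 7 with libraries 10 to 24, 1 with libraries 1 to 9, 0 with the epithelial level, 0 with an estimated correlation, 0 with fry and from 1 to 8 with single libraries left out. In HEV, from 0, they were 1 with no filter, 4 with all 24 libraries in 1 model and from 0 to 4 with single libraries left out. For the difference, from 2, they were 5 with the size factors of DESeq2, 5 with those of the labels, 5 with a count minimum of 50, 1 with the i5 index added, 0 with libraries 1 to 9, 0 with an estimated correlation, 0 with fry and from 1 to 5 with single libraries left out.

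The adjusted p of the collagen list in FRC (0.0014 to 1.00 over its alternatives) was 0.067 with no covariate, 0.10 with the i5 index added, 0.13 among libraries of a single i5 index, 0.10 with all 24 libraries in 1 model, 0.996 and in the other direction with libraries 1 to 9, 0.30 with the epithelial level, 0.43 with an estimated correlation, 0.26 with fry and from 0.0056 to 0.10 with single libraries left out. That of the epithelium list (1.64e-12 to 0.89) was 0.10 with the i5 index added, 0.89 and in the other direction with the epithelial level, which removes the signal of these same genes, 0.43 with an estimated correlation and 0.26 with fry. That of the TGF-beta list (0.00069 to 0.89) was 0.89 and in the other direction with libraries 1 to 9, 0.23 with the epithelial level, 0.43 with an estimated correlation, 0.26 with fry and from 0.0043 to 0.12 with single libraries left out. For the difference, that of the TGF-beta list (0.00084 to 0.90) was 0.895 and in the other direction with libraries 1 to 9, 0.64 with an estimated correlation, 0.24 with fry and from 0.00084 to 0.052 with single libraries left out. That of the ribosomal list (0.00023 to 0.90) was 0.46 with the i5 index added, 0.081 with the batch, 0.061 with libraries 10 to 24, 0.895 with libraries 1 to 9, 0.83 with an estimated correlation, 0.46 with fry and from 0.00023 to 0.24 with single libraries left out.

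These log2 fold changes of genes that had not passed changed sign. In FRC: with limma-voom Il7 (0.13); with no covariate Icam1 (0.04); with the i5 index added Ccl21a (-0.071) and Cxcl13 (0.24); among libraries of a single i5 index Ccl21a (-0.091) and Cxcl13 (0.17); with libraries 10 to 24 Il7 (0.14) and Cxcl13 (0.67). With libraries 1 to 9 they were Icam1 (0.15), Cxcl12 (-0.014) and Vcam1 (-0.23), and with the epithelial level Icam1 (0.16) and Il7 (0.35). Single libraries left out gave from -0.0056 to 0.080 for Pdpn, -0.11 to 0.043 for Icam1, -0.34 to 0.063 for Il7, -0.060 to 0.23 for Vcam1 and -0.48 to 0.031 for Cxcl13.

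In HEV they were Chst4 (-0.33) with limma-voom, and with the i5 index added Glycam1 (-0.10), Icam1 (0.19) and Vcam1 (0.25). Among libraries of a single i5 index they were Chst4 (-0.15), Glycam1 (-0.18), Icam1 (0.21) and Vcam1 (0.17), and with all 24 libraries in 1 model Fut7 (0.13), Icam1 (0.0020) and Selp (0.25). With the batch they were Icam1 (0.14), Vcam1 (0.072) and Piezo1 (0.033), and with libraries 10 to 24 Chst4 (-2.06), Glycam1 (-0.11), Icam1 (0.0023) and Piezo1 (0.18). Libraries 1 to 9 hold 1 HEV PEG library, assumed to vary like the 2 controls, and gave Fut7 (0.45), Icam1 (0.39), Madcam1 (0.35), Selp (0.38), Sphk1 (0.70) and Vcam1 (0.20). With the epithelial level they were Icam1 (0.078) and Vcam1 (0.00092). Single libraries left out gave from -0.0032 to 0.62 for Glycam1, -0.14 to 0.10 for Icam1, -0.51 to 0.0084 for Selp, -0.24 to 0.16 for Vcam1, -0.22 to 0.063 for Piezo1 and -0.52 to 3.64 for Chst4. For the difference Bmp4 was at -0.82 with libraries 1 to 9. Between the cell types Epcam was at 0.71 with the batch, 1.81 with libraries 1 to 9 and from -2.49 to 0.14 with single libraries left out, and Ptprc from -1.52 to 1.47.

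No marker list passed in any alternative for marker levels (exact permutation, 0 in each). In HEV the smallest p that the 210 splits can give is 0.0048, too large for a list on its own to pass once adjusted. Splits within pools in HEV (48), and the later libraries alone in both cell types, hold fewer splits still. The 0 was nearly fixed in advance there and tells little about marker levels. In FRC the smallest p over all 3432 splits is 0.00058, so a list could have passed. On simulated data, edgeR recovered 16.2% of 2-fold and 59.5% of 4-fold changes in FRC, 1.75% and 33.5% in HEV, 0.25% and 14.2% for the difference and 0.75% and 26.8% between the cell types, with at most 4 false calls, and camera called a list raised 1.5-fold in 4 of 4 simulations of each comparison. The simulated genes varied independently of each other and camera used the preset correlation. The simulations therefore cannot tell how reliable list calls are among genes that vary together, and other splits of the real FRC libraries called up to 7 lists.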

Other observations

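The contrast of libraries 1 to 9 with libraries 10 to 24, its genes and its lists were chosen after the data were seen, and these sets of samples are not groups of the study. With PEG in the model, 1836 genes differed between the sets in FRC (6 against 8 libraries; 823 higher and 1013 lower in libraries 10 to 24) and 377 in HEV (3 against 7; 125 higher and 252 lower). Of 12746 genes tested in both, 230 were called in both cell types, where 48.3 are expected by chance, and all 230 had the same direction. Lower in libraries 10 to 24 were the cell survival gene Bcl2l1 (log2 fold change -3.02 in FRC and -2.77 in HEV), the actin Actb (-0.75 and -1.17), Cdv3 (-2.25 and -2.26), the ribonuclease Ang (-2.41 and -6.24), the nucleotide synthesis enzyme Tyms (-2.76 and -2.77), Ubash3b (-4.99 and -4.71) and Lpcat1 (-2.90 and -2.43). Higher were the actin-binding Tmsb4x (1.44 and 1.41), Ubl5 (1.47 and 1.60) and Wdr89 (2.24 and 2.15).

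Oxidative phosphorylation genes were higher in libraries 10 to 24 in FRC (40 of 45 positive, median 0.62, adjusted p 6.76e-11; adjusted p = 0.26 with an estimated correlation) and in HEV (43 of 45, median 0.50, adjusted p 0.00013; adjusted p = 0.66 with an estimated correlation). NF-kappaB genes were lower in FRC (7 of 26 positive, median -0.57, adjusted p 0.0017; adjusted p = 0.26 with an estimated correlation) and in HEV (6 of 23 positive, median -0.56, adjusted p 0.015; adjusted p = 0.61 with an estimated correlation). Immediate early genes were lower in FRC (5 of 28 positive, median -1.04, adjusted p 9.46e-10; adjusted p = 0.32 with an estimated correlation), and in HEV had a median of -0.28 (adjusted p 0.22). Intestinal epithelium markers were higher in libraries 10 to 24 in FRC (20 of 20 positive, median 3.37, adjusted p 0.0017; adjusted p = 0.60 with an estimated correlation) and in HEV (19 of 21, median 2.45, adjusted p 0.0029; adjusted p = 0.66 with an estimated correlation), and myeloid markers lower in FRC (4 of 12 positive, median -0.91, adjusted p 0.022; adjusted p = 0.37 with an estimated correlation), with 1 of 7 positive and a median of -0.60 in HEV (adjusted p 0.11). Both sets of markers thus moved with the lists above in FRC, and the epithelial one in HEV. Cytosolic ribosomal protein genes were higher in FRC (66 of 82 positive, median 0.33, adjusted p 1.12e-05; adjusted p = 0.35 with an estimated correlation), with 62 of 82 positive and a median of 0.30 in HEV (adjusted p 0.11). Lower in FRC too were the unfolded protein response (9 of 23 positive, median -0.21, adjusted p 0.042; adjusted p = 0.37 with an estimated correlation), cholesterol synthesis (6 of 25, median -0.49, adjusted p 0.042; adjusted p = 0.26 with an estimated correlation) and collagen lists (13 of 34, median -0.15, adjusted p 0.047; adjusted p = 0.38 with an estimated correlation), and in HEV their adjusted p were 0.17, 0.92 and 0.56.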
